A study of Homo sapiens with 8 samples.

How the data were processed

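The data are a table of RNA read counts for 8 poly(A)-selected libraries, 1 for each of 4 treatments in each of 2 liver cancer cell lines. The counts were deposited by the authors as whole numbers of reads per Ensembl gene, with no normalization. Reads were processed with HISAT2 and HTSeq on GRCh38 (hg38), per the submitters' processing notes, whose versions are not given in the sources used here. Libraries were stranded, per the labels. The strand setting of the counting and the annotation release are not given in the sources used here, so reads of overlapping and antisense genes may not be told apart. Symbols and positions were taken from the deposited table, which holds 31710 genes. Each column was matched to its library by the title in the labels. The table held 0 columns of other samples.

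Counts were analysed as deposited in R 4.3.3. Genes with few reads were removed with filterByExpr on the treatment groups, which left 16972 genes and removed 14738. Libraries were scaled with TMM, and CPM values are TMM-scaled. Treatments were compared with edgeR 4.0.16 (estimateDisp, glmQLFit and glmQLFTest) in a model of cell line plus treatment over all 8 libraries, with 3 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. Standard errors were taken from the fold change and the F statistic. Differences between lines were tested in a model of cell line by XL413 plus cell line by sertraline, with 2 residual degrees of freedom. The spread in that model is how far the 2 drugs depart from additive effects inside a line. It is not the spread between lines or between repeated cultures. A positive value means a higher signed log2 change in Hep3B, which can be a larger rise or a smaller fall. The cell line is a term of the model because the 4 libraries of a line come from the same cells: deviations from the treatment means correlated with r of 0.89 to 0.94 between libraries of a line.

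Gene lists, the naming rule, the tests and the first group of alternatives given below were fixed before the data were examined. All 36 lists had at least 3 measured members and were tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and adjustment over the 36 lists of a comparison. Camera with an estimated correlation and fry were run beside it. No list was called with an estimated correlation in any comparison. Fry called 2 lists for XL413 (endothelial and immune markers) and 3 for sertraline (ATF4, fatty acid and lysosomal genes). For sertraline in pretreated cells it called 5 (those 3, sterol genes and immune markers), and for the interaction 0. Ratios inside 1 line compare 2 libraries, use a pseudocount of 0.5 CPM and have no replicate check or test.

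For XL413, sertraline, and sertraline in pretreated cells, the naming rule takes the 10 largest rises and the 10 largest falls among called genes with an average log2 CPM of at least 1, an official symbol and the same direction in both lines. Where fewer than 5 passed, it takes the 5 smallest p each way. It adds up to 4 members with the smallest p of each list called by camera, 10 genes in every comparison (some genes the rule takes and a list are not reported here), and the 5 smallest p each way for the interaction and each line difference.

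The depth of 20275392 to 30842770 reads per library limits the precision of genes with few reads, and counting error does not cover differences between cultures. The procedure was tested on simulated data drawn from the real means, library sizes and dispersions, with 200 of 16972 genes changed. For sertraline against control, 70 of 100 genes changed 1 log2 unit and 96 of 100 genes changed 2 log2 units were recovered, with 16 false calls among 182. For the line difference of the XL413 effect, 82 and 89 of 100 were recovered, with 2 false calls among 173. For the interaction, 27 and 82 of 100 were recovered, with 12 false calls among 121. Simulated libraries varied independently, without drug responses that differ between lines. For the interaction, 4.73% of unchanged simulated genes had an unadjusted edgeR p under 0.05, against 140 of 16972 genes in the data. The simulated rates may therefore not hold for the data.

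The first group of alternatives was DESeq2 size factors, total count scaling, no filter, a stricter filter, DESeq2 1.42.0, limma voom, robust empirical Bayes, a model without the cell line, an additive model, an adjusted p under 0.10, leaving out each library, and other pseudocounts and read minimums. Added after the data had been seen were drug effects inside 1 line, a model with line-specific drug effects, thinned libraries, leaving out each library in the line differences, and a list of YAP and TEAD targets. Figures were drawn with matplotlib 3.10.9.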

Results

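RNA was sequenced from 2 established human liver cancer cell lines, Huh7 and Hep3B. Each line was measured under 4 treatments, with 1 library per line and treatment and 8 libraries in all. The treatments were no drug (control), sertraline, XL413 for 10 days, and XL413 for 10 days followed by sertraline for 24 hours. The stated time of 24 hours refers to pretreated cells, and sertraline without XL413 was taken to have been given for as long. XL413 inhibits CDC7, a kinase that starts DNA replication, and the labels state that the pretreatment was meant to bring the cells into senescence, a lasting arrest of division. Sertraline is an antidepressant that blocks the serotonin transporter. Doses were not given in the sources used here. Total counts ranged from 20275392 reads, in the Hep3B library given XL413 alone, to 30842770 reads, in the Hep3B library given both drugs. Because no treatment was repeated inside a line, the 2 lines served as the replicates of each treatment. In comparisons of treatments, a p-value therefore sets a change against the spread of drug responses between these lines. Tests of line differences and of effects inside 1 line use another spread, described with them. Nothing in the labels says whether libraries of a line came from separate cultures.

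Levels of liver genes and of the drug target differed between the lines. AFP, the fetal serum protein used as a liver tumor marker, had 18604 ± 3460 CPM in Huh7 and 1009 ± 221 CPM in Hep3B (mean ± SD over the 4 libraries of a line, 1 per treatment). ALB, serum albumin, had 6688 ± 1107 CPM in Huh7 and 18467 ± 3218 CPM in Hep3B. SLC6A4, the serotonin transporter that sertraline blocks, was low in both lines, at 8.3 ± 2.76 CPM in Huh7 and 0.955 ± 0.199 CPM in Hep3B. Log2 CPM values of libraries of the same line correlated across genes with r from 0.97 to 0.99, and those of different lines with r from 0.86 to 0.88. Genes are not independent replicates in these correlations.

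Sertraline against control asks what the drug does to cells that were not pretreated. Genes of the ATF4 stress response, which is switched on by amino acid shortage and other stresses, rose together. Of 30 measured members 24 rose and none fell. TRIB3, a pseudokinase induced by stress (GRCh38 chromosome 20, 362835 to 397559), rose by 2.09 ± 0.11 on the log2 scale (SE), from 120 to 508 CPM in Huh7 and from 134 to 577 CPM in Hep3B. DDIT4, an inhibitor of mTORC1, rose by 2.21 ± 0.17. ASNS, asparagine synthetase, rose by 1.56 ± 0.12, and DDIT3, the transcription factor CHOP, by 1.61 ± 0.13. Adjusted over the list alone, 28 of the 30 rose. The list was higher in the camera test (adjusted p = 2.90e-26), and this call was lost with an estimated correlation (adjusted p = 0.229 with an estimated correlation). Fry called the list (fry adjusted p = 0.00659).

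Genes of sterol synthesis and uptake also rose after sertraline, 22 of 25 over all genes tested and 25 adjusted over the list alone. TM7SF2, a sterol reductase, rose by 1.86 ± 0.12 and EBP, a sterol isomerase, by 1.37 ± 0.15. HMGCS1, which makes the precursor of mevalonate, rose by 1.45 ± 0.16 and MVD, mevalonate diphosphate decarboxylase, by 1.81 ± 0.22. Of 15 genes of fatty acid synthesis 12 rose, 13 adjusted over the list alone. ACSS2, which makes acetyl-CoA from acetate, rose by 2.78 ± 0.25, from 146 to 771 CPM in Huh7 and from 81.2 to 698 CPM in Hep3B. PNPLA3, a lipase, rose by 1.91 ± 0.17, ELOVL6, a fatty acid elongase, by 1.66 ± 0.17, and FADS1, a desaturase, by 1.43 ± 0.18. The camera adjusted p was 1.84e-24 for the sterol list (adjusted p = 0.443 with an estimated correlation) and 1.79e-14 for the fatty acid list (adjusted p = 0.319 with an estimated correlation). Fry called the fatty acid list (fry adjusted p = 0.0367) and not the sterol list (fry adjusted p = 0.0586).

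Of 34 lysosomal genes 10 rose after sertraline, 20 adjusted over the list alone, and none fell. NEU1, lysosomal sialidase (chromosome 6, 31857659 to 31862906), rose by 2.47 ± 0.20, from 152 to 879 CPM in Huh7 and from 659 to 3526 CPM in Hep3B. LIPA, which splits cholesterol esters, rose by 1.45 ± 0.14, NPC2, which carries cholesterol out of the lysosome, by 1.30 ± 0.14, and ATP6AP1, a proton pump subunit, by 0.80 ± 0.11. The camera adjusted p was 4.28e-11 (adjusted p = 0.319 with an estimated correlation), and the fry adjusted p was 0.0367. Among 18 FOXO targets and mTORC1 regulators 5 rose, 10 adjusted over the list alone, including RRAGD, a GTPase of the mTORC1 pathway, by 1.73 ± 0.28, FLCN by 1.12 ± 0.19 and IRS2 by 1.14 ± 0.16. That list had a camera adjusted p of 1.42e-05 (adjusted p = 0.443 with an estimated correlation). Of 19 autophagy genes SQSTM1, a cargo receptor, rose by 1.01 ± 0.20 and ULK1, a kinase that starts autophagy, by 0.86 ± 0.19, and the other 17 were not called over all genes. Adjusted over the list alone 7 rose, and the camera adjusted p was 0.000947 (adjusted p = 0.567 with an estimated correlation).

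Genes of cell division fell after sertraline. Of 30 mitosis genes 15 fell over all genes tested, and adjusted over the list alone 28 fell and 1 rose. Those that fell included DLGAP5, by -0.88 ± 0.12, and KIF23, by -0.95 ± 0.14. Of 38 DNA replication genes 6 fell, 21 adjusted over the list alone, including the transcription factor E2F8 by -1.22 ± 0.18 and the ribonucleotide reductase subunit RRM2 by -1.17 ± 0.21. Of 15 DNA repair genes 3 fell, 8 adjusted over the list alone. The 3 were FANCD2, which fell by -0.63 ± 0.11, FANCI by -0.61 ± 0.11 and EXO1 by -0.83 ± 0.17. MKI67, the proliferation marker, had a log2 change of -0.63 ± 0.23 and was not called (edgeR adjusted p = 0.158). The 3 lists were lower by camera, with adjusted p of 1.59e-17 for mitosis, 7.35e-14 for replication and 6.03e-07 for repair. All 3 calls were lost with an estimated correlation (adjusted p = 0.449 for mitosis, 0.496 for replication and 0.482 for repair, each with an estimated correlation).

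Of 18 matrix and mesenchymal genes 4 fell after sertraline, 8 adjusted over the list alone. CTGF, a secreted matrix protein (chromosome 6, 131948176 to 131951373), fell most, by -2.74 ± 0.37, from 252 to 26.1 CPM in Huh7 and from 224 to 43.8 CPM in Hep3B. TPM1, a tropomyosin, fell by -1.30 ± 0.18, THBS1, thrombospondin, by -1.05 ± 0.23 and CDH2, N-cadherin, by -0.70 ± 0.14. The camera adjusted p of the list was 1.75e-06 (adjusted p = 0.496 with an estimated correlation). DUSP6 and SPRY4, feedback inhibitors of MAP kinase signalling, fell by -1.08 ± 0.17 and -1.05 ± 0.23. The metallothioneins MT1X and MT1E fell by -1.84 ± 0.34 and -1.34 ± 0.28, with under 2 CPM of each in Hep3B, and reads of this gene family can be split between near-identical members.

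Among the largest falls under the naming rule, NPPB, which encodes a natriuretic peptide, fell by -5.71 ± 0.68, from 78.4 to 0.695 CPM in Huh7 and from 8.97 to 0.631 CPM in Hep3B. EDN1, endothelin, fell by -4.20 ± 0.67, ANXA1, an annexin, by -3.64 ± 0.51, MMP24, a membrane metalloproteinase, by -2.54 ± 0.24, CXCL6, a chemokine, by -2.56 ± 0.51, and CXCR4, a chemokine receptor, by -2.51 ± 0.58. VSIG1 fell by -2.90 ± 0.30 and C14orf105 by -2.49 ± 0.29. GLIPR1 fell by -3.28 ± 0.45, a value carried by Huh7 (38.7 to 3.55 CPM), since Hep3B had 0.745 CPM in the control. Among the largest rises, IGFBP1, a secreted binding protein of insulin-like growth factors, went from 7.62 to 135 CPM in Hep3B and from 0.0765 to 1.1 CPM in Huh7. HSD17B14, a steroid dehydrogenase, rose by 2.81 ± 0.58, CATSPERG by 3.98 ± 0.41, TCP11L2 by 2.75 ± 0.50, DNAH17 by 2.81 ± 0.46 and TMPRSS9 by 2.75 ± 0.53. RASA4CP, LINC00957 and NT5DC4 rose by 4.14 ± 0.81, 3.55 ± 0.69 and 3.31 ± 0.67 from under 1 CPM in both controls. RASA4CP is a pseudogene that shares sequence with its parent genes, so its level is uncertain.

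In all, 831 of 16972 genes were called for sertraline against control (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 502 higher and 329 lower, and 825 of them had the same direction in both lines. The count was 89 without the Hep3B control library, 258 without the Huh7 control library, 322 without the Hep3B sertraline library and 553 without the Hep3B library of both drugs. No gene was called when the cell line was left out of the model, and 1611 were called by DESeq2. In edgeR 1585 were called without the low-count filter, 3399 in an additive model, which compares 4 libraries with 4, and 5629 in a model with line-specific drug effects, added after the data had been seen.

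**Figure D1:**
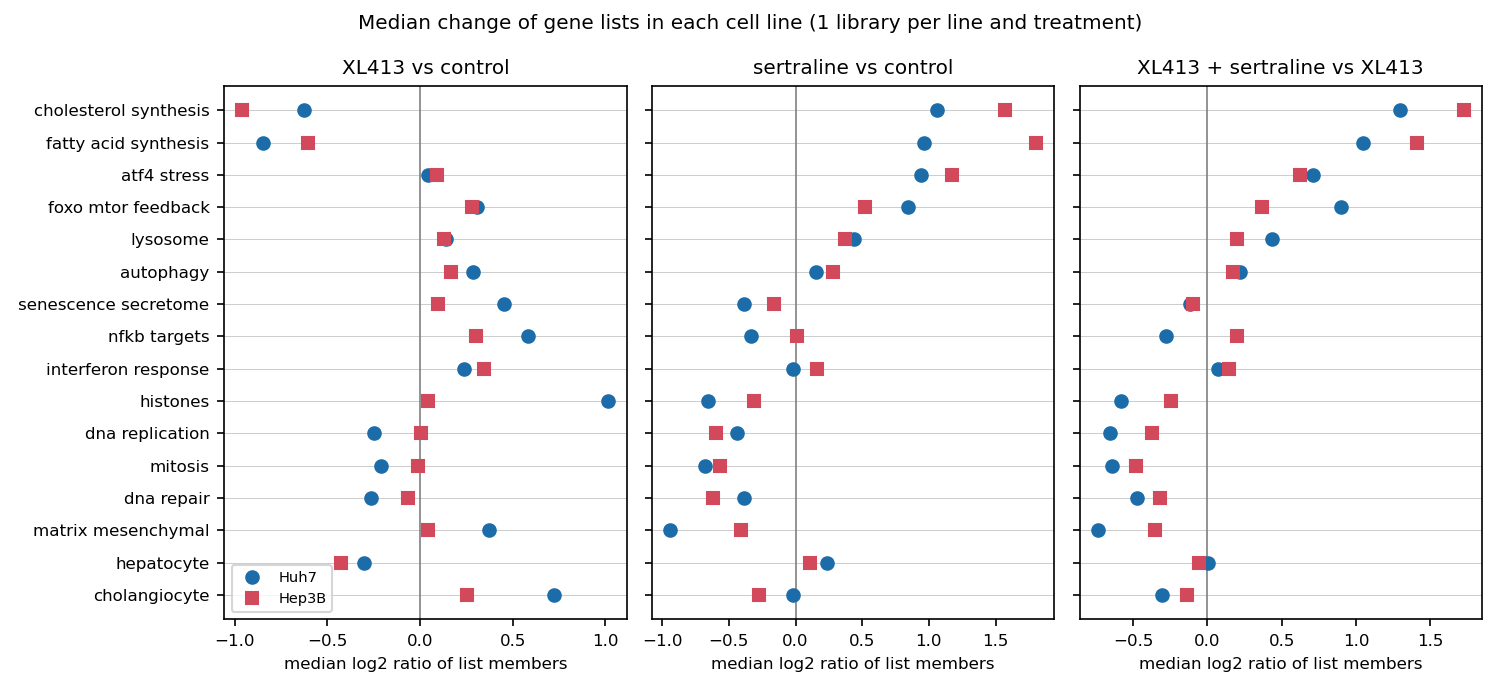
Median log2 ratio (horizontal axis) of the members of 16 gene lists (vertical axis) in Huh7 (circles) and Hep3B (squares), for XL413 against control, sertraline against control, and both drugs against XL413. Each point compares 2 libraries, and the sterol list has medians of 1.06 in Huh7 and 1.57 in Hep3B after sertraline and of -0.63 and -0.96 after XL413.

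Both drugs against XL413 alone asks what sertraline does to pretreated cells. Sterol synthesis genes rose again, 21 of 25, or 24 adjusted over the list alone. INSIG1, which holds back sterol synthesis, rose by 2.13 ± 0.24, and LSS, lanosterol synthase, by 1.95 ± 0.24. Of 15 fatty acid synthesis genes 6 rose, or 12 adjusted over the list alone, among them ACSS2 by 2.83 ± 0.25 and LPIN1 by 1.93 ± 0.27. Of 30 ATF4 genes 9 rose, or 24 adjusted over the list alone, led by TRIB3 at 1.85 ± 0.11, DDIT3 at 1.39 ± 0.12 and ASNS at 1.07 ± 0.12. Of 34 lysosomal genes 4 rose, or 14 adjusted over the list alone, including NEU1 by 2.07 ± 0.20 and NPC2 by 0.93 ± 0.14. Camera adjusted p was 8.37e-34 for the sterol list, 1.04e-22 for ATF4, 3.92e-16 for fatty acids and 3.40e-11 for lysosomes. These calls were lost with an estimated correlation (adjusted p = 0.328, 0.226, 0.273 and 0.273 in the same order, each with an estimated correlation). Fry called each of these lists (fry adjusted p = 0.0371, 0.0153, 0.0371 and 0.0371 in the same order).

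Of the mitosis genes 2 of 30 fell in pretreated cells, DLGAP5 by -0.81 ± 0.12 and KIF23 by -0.90 ± 0.14, and 27 fell when adjusted over the list alone. No DNA replication gene of 38 was called over all genes, and 21 fell when adjusted over the list alone. The camera adjusted p was 6.92e-20 for mitosis and 1.56e-16 for replication (adjusted p = 0.456 for both with an estimated correlation). NPPB fell by -3.33 ± 0.51, DKK1, a WNT inhibitor, by -1.73 ± 0.18, and TGFB2, a growth factor, by -1.46 ± 0.25. The Notch ligand JAG1 fell by -1.47 ± 0.21 and the glutamate transporter SLC1A3 by -1.35 ± 0.16. MMP24 fell by -1.88 ± 0.22, VSIG1 by -1.97 ± 0.30, SDPR by -1.54 ± 0.25 and GLIPR1 by -2.23 ± 0.37. CTGF had a log2 change of -1.95 ± 0.36 and was not called (edgeR adjusted p = 0.0531). Further rises were SLCO4C1 by 2.10 ± 0.30, SV2A by 1.97 ± 0.22, SH2D5 by 1.99 ± 0.34 and CATSPERG by 3.71 ± 0.35.

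The test called 159 genes, 113 higher and 46 lower, with 158 in the same direction in both lines. It called 2 genes without either library of both drugs, 27 without the Huh7 XL413 library and 87 without the Hep3B XL413 library, and it called 298 and 302 without the Huh7 and Hep3B sertraline libraries. DESeq2 called 810 (414 higher, 396 lower). In edgeR 830 were called without the low-count filter (453 higher, 377 lower) and 4483 with line-specific drug effects (2156 higher, 2327 lower). The excess of higher genes among the 159 therefore depends on the processing.

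Sertraline without and with pretreatment could be compared directly, since these comparisons share no library. All 113 genes higher with XL413 were among the 502 higher without it, where 3.34 would be shared by independent lists, and 45 of the 46 lower genes were among the 329, where 0.892 would be. Both tests use the same estimate of the spread of each gene, so the lists are not independent and these expected numbers are too low. All of the 502 and all of the 329 genes had the same sign with XL413. Across genes, the log2 ratios correlated with r = 0.79 in Huh7 and r = 0.73 in Hep3B. The test of the difference itself, the interaction of the drugs, called 0 of 16972 genes in edgeR, 0 in DESeq2 and 0 in limma voom. At an unadjusted p under 0.05 there were 140 genes, fewer than the 849 that chance gives. The spread in this test includes differences in drug response between the lines. A count so far below chance means that the test was conservative here, so 0 calls do not show that an interaction is absent. A model with line-specific drug effects was added after the data had been seen and leaves 1 residual degree of freedom. It called 160 genes and gave 1561 at an unadjusted p under 0.05. The genes with the smallest p included DDIT4, at -0.92 ± 0.23, CHAC1, which degrades glutathione, at -0.85 ± 0.22, PALMD at 1.07 ± 0.30 and HSD17B7, a sterol synthesis enzyme, at 0.60 ± 0.20. Among lists, camera called 12, 6 higher and 6 lower. ATF4 genes had a median interaction of -0.31 (camera adjusted p = 6.21e-15; adjusted p = 0.503 with an estimated correlation) and ribosomal protein genes of -0.22 (camera adjusted p = 2.46e-23; adjusted p = 0.722 with an estimated correlation). Among the higher lists, metallothioneins had a median of 0.40 (camera adjusted p = 0.000214; adjusted p = 0.722 with an estimated correlation) and sterol synthesis genes of 0.20 (camera adjusted p = 0.00635; adjusted p = 0.795 with an estimated correlation). The metallothionein median was 0.60 in Huh7 but -0.13 in Hep3B, so the value over both lines was carried by Huh7.

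XL413 against control asks what the pretreatment alone does. No gene was called in both lines together by edgeR (smallest adjusted p = 0.053), while 1828 genes had an unadjusted p under 0.05. DESeq2 called 203 genes and limma voom 0. In edgeR 238 were called without the low-count filter, and 1094 in an additive model, which compares the 4 libraries with XL413 with the 4 without it. A model with line-specific drug effects, added after the data had been seen, called 3032. The edgeR test called 3 genes without the Huh7 sertraline library, 3 without the Hep3B sertraline library and 2 without the Huh7 XL413 library. The lowest p among higher genes belonged to NDRG1, a stress-induced gene, at 1.49 ± 0.15, from 79.2 to 195 CPM in Huh7 and from 30.8 to 100 CPM in Hep3B, to C7, a complement component, at 2.17 ± 0.24, to SPOCK2 at 1.78 ± 0.20, to PGC at 2.30 ± 0.27, and to TPPP3, seen almost entirely in Hep3B (0.426 to 15.2 CPM, against 0.0382 to 0.281 CPM in Huh7). Among lower genes it belonged to ATP2B2, a calcium pump, at -0.95 ± 0.12, PAQR9 at -0.95 ± 0.12, HSD17B7 at -1.11 ± 0.15, ELOVL6 at -1.12 ± 0.17 and CPN1 at -1.07 ± 0.17. None of these passed the threshold.

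Sterol synthesis genes were lower as a list after XL413, with a median log2 change of -0.78, and all 25 members were below 0 in both lines. Adjusted over the list alone 22 fell, such as HMGCS1 at -0.97 ± 0.16 and INSIG1 at -1.30 ± 0.24. Fatty acid synthesis genes had a median of -0.75, and 9 of 15 fell when adjusted over the list alone, including GPAM at -1.34 ± 0.22 and ACACA at -0.58 ± 0.12. Hepatocyte genes had a median of -0.34, with F2, prothrombin, at -0.66 ± 0.15 and APOB at -0.61 ± 0.16, while TTR, transthyretin, was at 0.85 ± 0.19. Camera adjusted p was 2.61e-24 for the sterol list, 8.54e-14 for fatty acids and 3.26e-08 for hepatocyte genes (adjusted p = 0.499, 0.453 and 0.262 in that order, each with an estimated correlation). Camera called 22 of the 36 lists for XL413, 11 higher and 11 lower. The lower lists included mitosis genes, with medians of -0.21 in Huh7 and -0.01 in Hep3B, and DNA replication genes, with -0.25 and 0.01. Lists higher by camera included NF-kappaB targets, with a median of 0.66 (adjusted p = 0.00201; 0.539 as adjusted p with an estimated correlation), and senescence-associated secreted factors, with a median of 0.40 (adjusted p = 0.00893; 0.539 as adjusted p with an estimated correlation). These lists share genes and are not separate results. The median ratio of the secreted factors was 0.455 in Huh7 and 0.0999 in Hep3B, and over both sertraline settings the list was not called inside Hep3B (camera adjusted p = 0.323). Of the secreted factors 3 rose when adjusted over the list alone. ICAM1, an adhesion molecule that is also on the NF-kappaB list, was at 0.81 ± 0.13.

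Markers of other cell types were mostly low. The cholangiocyte list was higher after XL413, with a median of 0.80 (camera adjusted p = 8.27e-05; adjusted p = 0.501 with an estimated correlation), where KRT19 went from 220 to 357 CPM in Huh7 and from 296 to 351 CPM in Hep3B. Only 3 immune markers passed the filter, and LYZ, also made by epithelial cells, had the most reads, going from 404 to 481 CPM in Huh7 and from 70.6 to 132 CPM in Hep3B after XL413. These 3 were higher as a list after XL413, with a median of 0.60, by camera (adjusted p = 0.0239; adjusted p = 0.501 with an estimated correlation) and by fry (adjusted p = 0.0329). Of 5 endothelial markers 3 were above 0 and 2 below after XL413, and the list was called by fry (adjusted p = 0.0395) but not by camera (adjusted p = 0.176). EGFL7 and PECAM1, with the most reads, went from 28 to 21.8 CPM and from 6.2 to 3.65 CPM in Huh7. In Hep3B they went from 8.83 to 9.56 CPM and from 1.28 to 0.895 CPM. The markers with a fitted value above 0, VWF, CDH5 and LYVE1, had under 2 CPM in every library. In the Hep3B control and XL413 libraries each had at most 1 read, so their rise was seen in Huh7 alone. Stellate cell markers were tested with 7 genes, of which 1, PDGFRB, fell with sertraline in pretreated cells. That list was lower with a camera adjusted p of 0.0391 (adjusted p = 0.456 with an estimated correlation). Its median ratio was -0.47 in Huh7 but 0.17 in Hep3B, so the lines went opposite ways.

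CDC7, the kinase that XL413 inhibits (chromosome 1, 91500893 to 91525764), was at -0.19 ± 0.16 after XL413 and its partner DBF4 at -0.12 ± 0.17. CDKN1A, the cell cycle inhibitor p21, was at 1.38 ± 0.34 (edgeR adjusted p = 0.243), CDKN2A at 0.04 ± 0.25, LMNB1, a lamin that is lost in senescent cells, at -0.37 ± 0.18 and MKI67 at -0.17 ± 0.23. MKI67 went from 456 to 333 CPM in Huh7 and from 448 to 491 CPM in Hep3B, so the value over both lines joins opposite directions. The same holds for CDKN2A, which went from 28.3 to 26 CPM in Huh7 and from 52 to 61.4 CPM in Hep3B. It also holds for DBF4, which went from 53 to 42.8 CPM in Huh7 and from 46.5 to 47.7 CPM in Hep3B. None of these 6 genes was called after XL413 alone. After sertraline alone CDC7 was at -0.61 ± 0.16 (edgeR adjusted p = 0.0704), LMNB1 at -0.69 ± 0.18 (edgeR adjusted p = 0.07) and CDKN1A at 1.12 ± 0.34 (edgeR adjusted p = 0.102), and these were not called. With both drugs against control, CDKN1A rose by 1.70 ± 0.34 (edgeR adjusted p = 0.0254) and LMNB1 fell by -0.95 ± 0.18 (edgeR adjusted p = 0.0231).

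**Figure D2:**
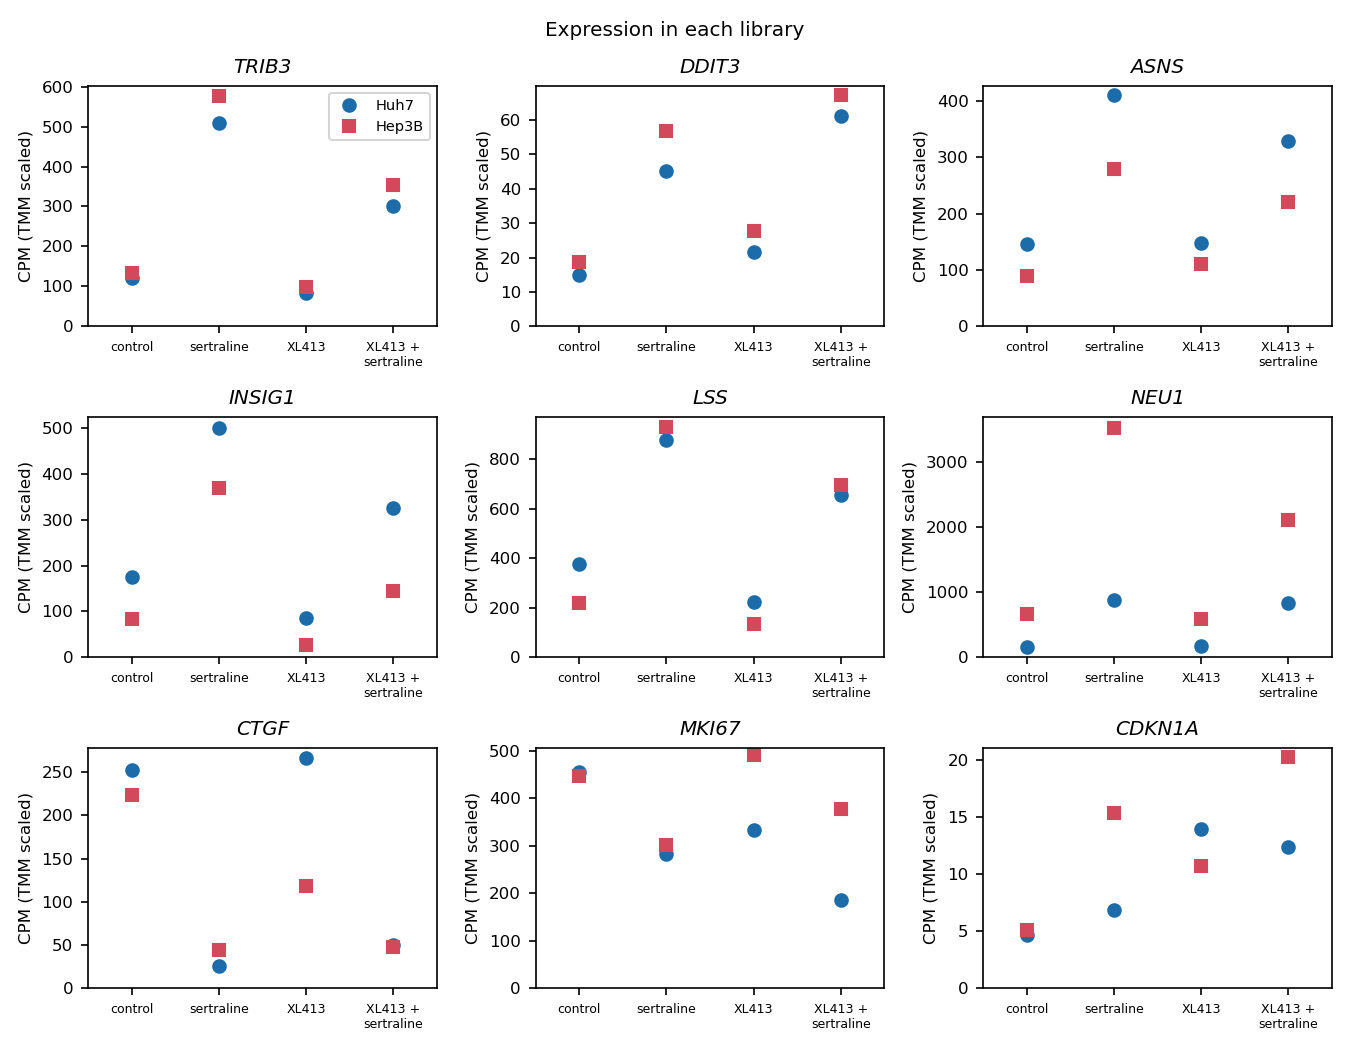
TMM-scaled CPM (vertical axis, from 0) of 9 genes in each library (horizontal axis, treatment), with Huh7 as circles and Hep3B as squares; each point is 1 library. TRIB3 lies at 508 CPM in Huh7 and 577 CPM in Hep3B after sertraline, against 120 and 134 CPM in the controls.

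Both drugs against control called 1564 genes, 822 higher and 742 lower. Of 30 mitosis genes 23 fell and of 38 replication genes 15 fell, while 20 of 30 ATF4 genes and 17 of 34 lysosomal genes rose. Of 25 sterol synthesis genes 8 rose. Adjusted over the list alone 28 mitosis and 32 replication genes fell, and 26 ATF4, 20 lysosomal and 17 sterol genes rose. Camera adjusted p was at most 2.81e-09 for these lists, and no call held with an estimated correlation (adjusted p = 0.267 for ATF4 and lysosomes and 0.452 for the others, each with an estimated correlation). Of these lists, fry called ATF4 (fry adjusted p = 0.0168) and lysosomes (fry adjusted p = 0.0265) and none of the others. With total count scaling, which moved the median of all genes by 0.12, the split was 1214 higher and 375 lower. The count fell to 6 without the Huh7 library of both drugs, 55 without the Hep3B control library, 277 without the Huh7 control library and 402 without the Hep3B library of both drugs, and DESeq2 called 2455. In edgeR 2505 were called without the low-count filter and 6899 with line-specific drug effects.

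Whether the lines responded alike was tested with the difference of each drug's effect between lines, averaged over both settings of the other drug. The p-values of this test are set against departures of the 2 drugs from additive effects inside a line. They do not cover the spread between repeated cultures. The XL413 effect differed in 1510 genes (669 with the higher signed change in Hep3B, 841 with the higher signed change in Huh7). A higher signed change can be a larger rise or a smaller fall. DNA replication genes differed as a list, with 15 of 38 called: their median log2 ratio was -0.33 in Huh7 and 0.13 in Hep3B (camera adjusted p = 5.04e-16; adjusted p = 0.529 with an estimated correlation). Histone genes had a median of 1.13 in Huh7 and -0.02 in Hep3B, with 9 of 13 called (camera adjusted p = 1.25e-07; adjusted p = 0.494 with an estimated correlation). Reads of histone genes can be shared between copies, and most of these transcripts lack a poly(A) tail. NR1H4, the bile acid receptor, had ratios of -0.84 in Huh7 and 1.13 in Hep3B, and TXNIP, an inhibitor of thioredoxin, of 2.03 in Huh7 and 0.05 in Hep3B. Across genes, XL413 log2 ratios of the lines correlated with r = 0.27, against r = 0.57 for sertraline. XL413 also gave fewer 2-fold genes, 338 in Huh7 and 276 in Hep3B, against 585 and 706 for sertraline. Noise lowers r more where changes are small, so the lower r alone does not show less agreement between the lines. The count of 1510 was 835 without the Huh7 control library, 508 without the Huh7 sertraline library, 859 without the Huh7 XL413 library and 496 without the Huh7 library of both drugs. DESeq2 called 746.

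The sertraline effect differed between lines in 737 genes (437 with the higher signed change in Hep3B, 300 with the higher signed change in Huh7). Among the genes with the smallest p, MYL9, a myosin light chain, had ratios of -2.78 in Huh7 and -0.83 in Hep3B, TAGLN, transgelin, of -4.16 and -1.66, and TPM2, a tropomyosin, of -1.83 and -0.26. Each of them thus fell more in Huh7. Sterol genes rose more in Hep3B, with 9 of 25 called and medians of 1.16 in Huh7 and 1.65 in Hep3B (camera adjusted p = 1.49e-13; adjusted p = 0.564 with an estimated correlation). The count of 737 was 210, 222, 270 and 265 without the Huh7 control, sertraline, XL413 and both-drug library in that order, and 1737 and 1738 without the Hep3B XL413 and both-drug libraries. With total count scaling it was 476 (254 with the higher signed change in Hep3B, 222 with the higher signed change in Huh7), and DESeq2 called 382.

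Drug effects inside each line, from the same fit, were examined only after the data had been seen. XL413 was tied to 3487 genes in Huh7 (1961 higher, 1526 lower) and 2894 in Hep3B (1501 higher, 1393 lower), and sertraline to 4730 in Huh7 (2429 higher, 2301 lower) and 4083 in Hep3B (1999 higher, 2084 lower). Each effect rests on 2 libraries against 2 of 1 line, and where the XL413 libraries of a line came from 1 pretreated culture they are not independent. The spread is again the departure of the drugs from additive effects inside a line, so these counts cannot be set beside those over both lines. DESeq2 called 1696, 1402, 2997 and 2488 genes in that order. In Huh7, leaving out the control, sertraline, XL413 or both-drug library gave 1514, 887, 1513 and 870 genes for XL413 and 2398, 2427, 1861 and 1852 for sertraline. In Hep3B the sertraline count was 1456 without the control library and 1503 without the sertraline library. With total count scaling, which moved the median of all genes by 0.10 in Huh7 and 0.11 in Hep3B, XL413 was tied to 2542 higher and 691 lower genes in Huh7 and to 2470 higher and 689 lower in Hep3B.

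**Figure D3:**
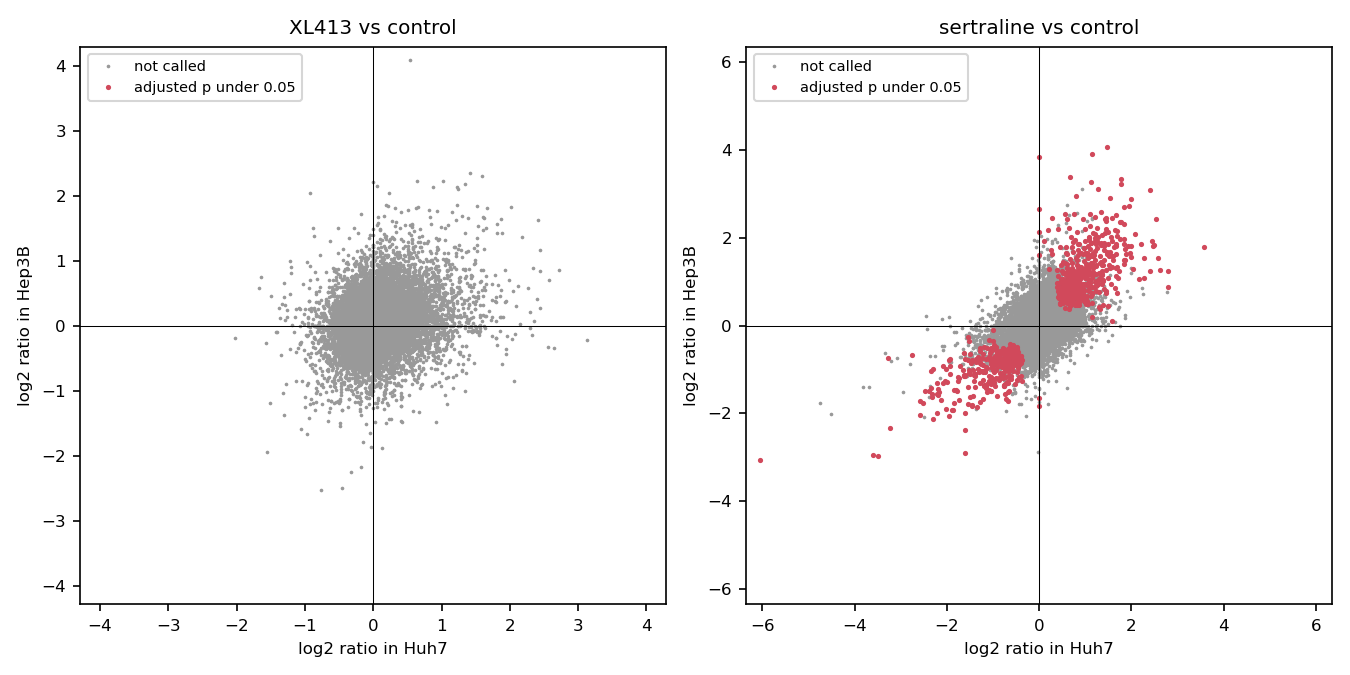
Log2 ratio of CPM in Hep3B (vertical axis) against Huh7 (horizontal axis) for 16972 genes, after XL413 (left) and after sertraline (right), each against control; grey points were not called and red points have an adjusted p under 0.05. The left panel has 0 red points and the right panel 831, of which 825 have the same direction in both lines.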

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

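The tests of depth for the XL413 difference, of a single aberrant library for the sterol genes, of scaling, of the sertraline response line by line and of splits of the libraries were chosen only after the result was seen; the test of a single aberrant library for the XL413 difference and the pooled tests of smaller sertraline changes, depth included, were written down before theirs.

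The XL413 effect differed between lines in 1510 genes and the sertraline effect in 737. A higher signed change, as given here, can be a larger rise or a smaller fall. For XL413, the signed change was higher in Hep3B, by the log2 difference given, for THBS4 (1.86), NR1H4 (1.99), BGN (1.73), PKI55 (1.76) and AUTS2 (1.99). It was higher in Huh7 for GPX2 (-2.32), IGSF1 (-1.80), TXNIP (-2.05), SERPINC1 (-2.19) and PEG10 (-1.82). For sertraline, the signed change was higher in Hep3B for SLC7A7 (2.12), MYL9 (1.95), CSRP1 (1.55), TPM2 (1.57) and TAGLN (2.42). It was higher in Huh7 for UAP1L1 (-1.51), SECTM1 (-1.87), TMEM144 (-1.51), RAB29 (-1.26) and ASAH1 (-1.19). MYL9, TPM2 and TAGLN fell in both lines, and more in Huh7.

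Lists whose XL413 effect differed between lines by camera had these median log2 differences, Hep3B minus Huh7. The medians were 0.42 for DNA replication, 0.26 for mitosis, 0.26 for DNA repair and 0.10 for ribosomal proteins. They were -1.12 for histones, -0.78 for matrix genes, -0.69 for senescence-associated secreted factors, -0.51 for NRF2 targets, -0.51 for the interferon response, -0.46 for mitochondrially encoded genes, -0.45 for immediate early genes and -0.43 for cholangiocyte markers. They were -0.35 for NF-kappaB targets, -0.33 for autophagy, -0.31 for sterol synthesis, -0.21 for LXR targets, -0.16 for oncofetal genes and -0.14 for endoplasmic reticulum chaperones. For sertraline the medians were 0.94 for stellate cell markers, 0.58 for matrix genes, 0.49 for NF-kappaB targets, 0.47 for fatty acid synthesis, 0.42 for sterol synthesis, 0.42 for histones, 0.41 for secreted factors, 0.33 for chaperones, 0.29 for mitochondrially encoded genes and 0.13 for mitosis. They were -0.48 for FOXO and mTORC1 genes, -0.30 for ribosome biogenesis, -0.29 for bile acid and drug metabolism, -0.25 for heat shock proteins and -0.16 for lysosomes. With an estimated correlation none of these lists was called, and the adjusted p with an estimated correlation was at least 0.494 for each.

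The first pattern is the XL413 response, which differed between lines in 1510 genes over both sertraline settings. Over both settings the additive model also called 1094 genes for the lines together, so the count of 1510 does not mean that the lines had no response in common. The Hep3B XL413 library had the fewest reads, yet with all libraries thinned to its depth 1504 genes were called, 1335 of them among the 1510. Among 540 genes with a line difference of at least 2-fold without sertraline, 96.7% had the same sign in the libraries with sertraline, and among 669 chosen with sertraline 95.4% had the same sign without it, which argues against a single aberrant library. What stays open is separate handling of the cultures of each line: the 2 libraries of a line and XL413 setting may share 1 pretreated culture, so a difference between cultures and a difference between lines cannot be told apart. A biological difference between the lines stays open and untested.

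The second pattern is that the sertraline changes were smaller with XL413, with a median size of 1.02 log2 units without and 0.74 with it over the 831 called genes. The sterol list went the other way. Its median ratio was 1.06 without and 1.30 with XL413 in Huh7, and 1.57 and 1.73 in Hep3B. Genes called for the effect averaged over both settings are not chosen for this direction, and 69.8% of these 3399 still had the smaller change with XL413, or 70.2% with thinned libraries, which argues against selection and depth as the whole cause of the pooled value. The lines differed, however. In Hep3B the share was 91.0% of the 831 genes and 79.7% of the 3399. In Huh7 it was 68.4% of the 831 but 44.7% of the 3399, so there selection of the genes could account for the smaller change among the 831, and over the 3399 no smaller change was seen. In Hep3B a single aberrant library cannot be told apart from an effect of XL413, since there is 1 library per treatment. The interaction called 0 genes, but it gave fewer low p-values than chance does, so that test does not decide the question.

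The third pattern is that sterol synthesis genes were lower after XL413 and higher after sertraline. A single aberrant library would leave 1 of 2 comparisons that share no library without the change. Both drugs against sertraline alone, which shares no library with XL413 against control, gave medians of -0.42 in Huh7 and -0.66 in Hep3B, with all 25 genes lower in both lines. Both drugs against XL413 alone, which shares none with sertraline against control, gave 1.30 and 1.73, with all 25 genes higher in both lines. These values argue against a single aberrant library as the whole cause of either change. With total count scaling the median for XL413 against control was -0.71, against -0.78. Culture time or density stays open and cannot be told apart from XL413: 0 libraries without XL413 have a stated culture time.

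With 4 libraries with and 4 without a drug, there are 18 splits that keep 2 libraries of each line on each side, too few for a share under 0.05. The sertraline split called 1676 genes and was the only 1 with as many, against 9 for the highest other, which is the XL413 split. The XL413 split called 9, and 2 splits, itself and the sertraline split with 1676, called as many. Splits other than the sertraline split leave the sertraline effect in the spread, so their low counts decide nothing, and with sertraline in the model XL413 called 1094.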

How the results depend on the processing

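The model with line-specific drug effects, thinned libraries, leaving out libraries in the line differences and drug effects inside 1 line were chosen only after the data had been seen; the other alternatives were chosen earlier. DESeq2 size factors, the stricter filter, robust empirical Bayes and limma voom moved no total of called genes by over 1.5 times, but limma voom called 88 lower genes for sertraline in pretreated cells against 46. The cause of the changes below was not tested, except where the alternative itself sets it.

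Without a low-count filter XL413 against control called 238 genes, sertraline against control 1585, sertraline in pretreated cells 830 and both drugs 2505; the sertraline calls were then 870 higher and 715 lower and included 830 of the 831. At an adjusted p under 0.10 the counts were 7, 1677, 447 and 3133 in that order, and 2294 and 1124 for the line differences of XL413 and sertraline. DESeq2's Wald test called 203, 1611, 810 and 2455 in the same order, 746 and 382 for the line differences, 1696 and 1402 for XL413 inside Huh7 and Hep3B, and 2997 and 2488 for sertraline inside Huh7 and Hep3B. Of the 831 sertraline genes 786 were among the DESeq2 calls. With no replicate block, which puts the difference between lines into the residual, 0 genes were called for sertraline, for sertraline in pretreated cells and for both drugs; this is the pairing by cell line, and XL413 and the interaction stayed at 0. The additive model, with 4 libraries against 4, called 1094 genes for XL413 and 3399 for sertraline. With line-specific drug effects, which leave 1 residual degree of freedom and take the differences between lines out of the spread, the counts were 3032 for XL413, 5629 for sertraline, 4483 for sertraline in pretreated cells, 160 for the interaction and 6899 for both drugs. Total count scaling called 2 genes for XL413 and 476 for the line difference of sertraline, split into 254 higher and 222 lower against 437 and 300. It split the calls for both drugs into 1214 higher and 375 lower against 822 and 742, those for XL413 inside Huh7 into 2542 and 691 against 1961 and 1526, and those inside Hep3B into 2470 and 689 against 1501 and 1393. Thinned libraries called 5 genes for XL413.

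Leaving out 1 library at a time gave 0 to 3 genes for XL413, 89 to 682 for sertraline, 2 to 302 for sertraline in pretreated cells, 6 to 1793 for both drugs, 496 to 1899 for the line difference of XL413 and 210 to 1738 for that of sertraline. Inside lines it gave 870 to 4919 for XL413 in Huh7, 1852 to 5952 for sertraline in Huh7 and 1456 to 4760 for sertraline in Hep3B. A comparison of treatments that loses a library has 1 library left of that treatment, which is assumed to vary like the others. In the model of line differences and effects inside 1 line, the line that loses a library is fitted exactly. Its effects then rest on its own remaining libraries, and the spread comes from the other line alone.

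List medians that changed sign without 1 library had these ranges. For XL413 they were -0.25 to 0.0050 for DNA replication, -0.25 to 0.0068 for mitosis, -0.089 to 0.48 for matrix genes and -0.43 to 0.038 for heat shock proteins. For sertraline the range was -0.50 to 0.036 for immediate early genes. For sertraline in pretreated cells they were -0.84 to 0.14 for histones, -0.47 to 0.21 for immediate early genes and -0.91 to 0.31 for stellate cell markers. For the interaction they were -0.071 to 0.37 for endoplasmic reticulum chaperones, -0.095 to 0.55 for sterol synthesis, -0.28 to 0.70 for matrix genes, -0.22 to 0.0019 for the respiratory chain, -0.98 to 0.60 for metallothioneins, -0.055 to 0.37 for ribosome biogenesis and -0.020 to 0.27 for DNA repair. Without a filter the interaction median of matrix genes was -0.040. Of 200 list calls, 34 held with fry and 0 with an estimated correlation.

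The number of genes with a 2-fold ratio inside 1 line depends on the read minimum and pseudocount. For XL413 it was 338 in Huh7 and 276 in Hep3B, and 148 and 152 with a minimum of 200 reads or 149 and 141 with a pseudocount of 2 CPM. With a pseudocount of 2 CPM it was 457 for sertraline in Hep3B against 706, 397 and 147 for sertraline in pretreated Huh7 and Hep3B against 603 and 233, and 595 and 403 for both drugs in Huh7 and Hep3B against 969 and 719. With a minimum of 200 reads it was 631 for both drugs in Huh7.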

Other observations

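The test of YAP and TEAD targets was chosen only after the result was seen.

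Ribosomal protein genes had a median log2 change of -0.13 after XL413 and 0.20 after sertraline, with none of 76 called in either, also adjusted over the list alone. The list was called by camera in both (adjusted p = 5.14e-09 and 3.27e-08) but not with an estimated correlation (adjusted p = 0.501 and 0.583 with an estimated correlation). Of 10000 random lists matched on size and expression, 1.5% in Huh7 but 65.5% in Hep3B had a lower median after XL413. The fall after XL413 thus stood apart only in Huh7. After sertraline 100% had a lower median in each line. Total count scaling moved the median of all genes by 0.08 for XL413. Nuclear genes of the respiratory chain had a median of -0.23 after sertraline in pretreated cells, with none of 35 called, also adjusted over the list alone (camera adjusted p = 1.82e-07; adjusted p = 0.456 with an estimated correlation). CYP3A7, a fetal drug-metabolizing enzyme, rose by 1.84 ± 0.32 with sertraline in pretreated cells, from 6.21 to 36.1 CPM in Huh7 and from 5.14 to 11.1 CPM in Hep3B. XL413 and sertraline log2 ratios, which share the control library, correlated across genes with r = -0.0060 in Huh7 and r = 0.27 in Hep3B, where simulated unchanged groups gave 0.50 and 0.49. The covariance was -0.0010 in Huh7 and 0.0495 in Hep3B, against 0.0497 and 0.0491 in the simulation. The simulated covariance depends on the spread put in. The close value in Hep3B therefore does not show that the drugs share only the control.

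CTGF and EDN1 fell after sertraline, and a hypothesis is that lower expression of YAP and TEAD target genes, a program tied to the cytoskeleton, may be part of the response. Of 19 other target genes 18 were measured. Their median log2 change was -0.95 after sertraline, 15 were below 0, and 2 fell over all genes tested, CRIM1 by -1.66 and AMOTL2 by -1.73. Camera gave p = 7.69e-06 with the preset correlation, but p = 0.117 with an estimated correlation, and fry gave p = 0.0535, so the hypothesis rests on the preset correlation. In pretreated cells the median was -0.79 (camera p = 0.000335, and p = 0.179 with an estimated correlation). No protein or activity was measured.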
